A study of Homo sapiens with 17 samples.

How the data were processed

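Nalm-6 cells are an established human pre-B leukaemia line. Per the labels' protocols, a clone with inducible Cas9 received doxycycline for 8 days, was expanded in spinner flasks and was then grown for 8 days in flasks with compound; genomic DNA was extracted and the sgRNA locus was amplified by PCR and sequenced. The deposited values are raw read counts per sgRNA in 2 columns, the samuraciclib library (0.35 uM) and the combined controls, as the authors made them and per the file headers. Per the labels, all 16 control libraries belong to the combined column, so they could not be compared by day or vehicle, and a planned description of the controls over time and vehicle was not run. How the control libraries were combined is not stated; the column holds whole numbers and was treated as a sum of reads, on which the depth ratio and the intervals from counts rest. The read counter and its version, the matching rule for reads and the genome build are not given in the sources used here. PCR reads without molecular identifiers are not independent molecules, so intervals from counts cover counting error only.

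The file named 192613 sgRNAs of 20 bases by their sequence and target: 19907 target names, of which 1067 join several genes (2896 sgRNAs), and 2041 non-targeting sgRNAs. It gives no positions of sgRNAs in the genome, and none were assigned. Of the target names, 17466 are current symbols and 1343 are synonyms only in the RefSeq gene table of assembly GRCh38.p14, which was used for names alone; symbols are printed as in the file, some of them older. Of the members of the gene lists, 2 were not found (BCL2L2 and NDUFC2).

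Control counts were scaled to the depth of the treated library, 0.5 reads were added to both sides, and the log2 ratio was centred on its median over sgRNAs (uncentred median −0.03; non-targeting sgRNAs after centring 0.03). sgRNAs with at least 20 control reads entered (191999, with 614 left out), and targets with at least 4 of them (18915, with 992 left out; 270 of the tested names join several genes). Within 50 bins of control count, the log2 ratios were ranked and turned into normal scores, and a target's score was the mean over its sgRNAs. The two-sided permutation p compared it with 1000000 random draws of as many sgRNAs from all sgRNAs, with a smallest p of 1e-06 that 29 targets reached, and Benjamini-Hochberg adjustment over 18915 targets at 0.05. Without adjustment, 1672 targets had a permutation p below 0.05. Fold changes are means over sgRNAs with their SD. A ratio of summed reads carries an exact (Clopper-Pearson) binomial interval at 95%.

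The test assumes that sgRNAs of one target are independent, and has no replicate culture behind it. It was tested on simulated counts at the depths of these columns, with 200 changed targets among 18915. All sgRNAs of a changed target shared its change, and every sgRNA had an extra SD of 0.31, estimated from non-targeting sgRNAs. In this simulation 36 of 50 targets at log2 0.5, 33 of 50 at −0.5 and all 50 at each of 1 and −1 were called. Of 18715 unchanged targets, 5 were called. On the real counts, 204 sets of 10 non-targeting sgRNAs gave 9 (4.41%) at an unadjusted permutation p below 0.05 and none called.

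The 39 gene lists, the test, the first set of alternatives and the rule for named genes were chosen before the data were examined. A list is described by the median of its targets' log2 fold changes and the percentile of that median among 10000 random lists of the same size matched on control count in 20 bins, and is called shifted below percentile 2.5 or above 97.5. This is a description of these libraries and carries no p. Of the 39 lists, 6 were shifted higher, 10 lower and 23 neither. The rule names CDK7, CCNH and MNAT1 whatever their values, the 12 called targets with the highest and the 12 with the lowest fold changes, up to 4 called members per list by size of the fold change, and any called member of a list with 5 or fewer. It gave 56 genes, some of which are not reported here. Other members are named with values as partners of these, after their values were seen. The ribosome list keeps annotated paralogs of ribosomal proteins.

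Alternatives were a pseudocount of 5 reads, at least 1 or 100 control reads, ranks without bins, the median normal score, leaving out the sgRNA farthest from the target median, a null from non-targeting sgRNAs, counting an sgRNA that names several genes for each of them, no centring, centring on olfactory receptor sgRNAs and a threshold of 0.01; for lists, also the median over sgRNAs and unmatched random lists. The file holds no separate alternative-exon targets, so the planned merging of such targets became the counting for each named gene. Ranks within bins of control count and GC content, list medians without centring or centred on olfactory receptors, and list medians of the mean normal score were added after seeing the data. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.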

Results

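The screen measured how often each single guide RNA (sgRNA) was found in the genomic DNA of Nalm-6 cells, a human pre-B lymphoid leukaemia cell line, carrying a genome-wide knockout library and a doxycycline-inducible Cas9. After Cas9 induction the culture was divided into flasks, and 1 flask was grown for 8 days with 0.35 uM samuraciclib (also called ICEC0942), an inhibitor of the cyclin-dependent kinase CDK7. The control side held 16 libraries that had been combined into 1 column of counts: 2 each from DMSO, ethanol and untreated flasks at day 8, and 2 each from spinner flasks at days 0, 2, 4, 6 and 8. The samuraciclib library held 11110749 reads, with a median of 48 reads per sgRNA and 2113 of 192613 sgRNAs (1.10%) at 0 reads. The combined control column, treated here as a sum of reads, held 271643014, 24.4 times as many, with a median of 1194 per sgRNA and 1 sgRNA at 0. Most targets carried 10 sgRNAs (17309 of 19907 target names), and 18915 targets were tested.

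The comparison asks which gene knockouts became more or less abundant in samuraciclib than in the combined controls. Members of the mitochondrial ribosome, of respiratory complex I and of mTORC2 rose, and negative regulators of mTORC1 fell. Beyond mTORC2 members, the only called activator of the PI3K pathway was PDPK1, whose call was lost under 3 alternatives. sgRNAs against 216 targets (1.14%) changed, 162 of them higher and 54 lower, by a two-sided permutation test over sgRNAs with Benjamini-Hochberg adjustment at 0.05. Mean log2 fold changes of the targets that rose ran from 0.32 to 1.04, and of those that fell from −2.10 to −0.46. With only 1 treated library and 1 pooled control column, the test compares these columns of reads and not the conditions, and errors are SDs over a target's sgRNAs, not over cultures. The count was 109 (78 higher, 31 lower) when the median normal score replaced the mean, and with a null drawn from non-targeting sgRNAs it was 235, split into 151 higher and 84 lower. The control column also includes days before the endpoint, so a fall can hold loss of a knockout over time as well as an effect of the compound.

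**Figure D1:**
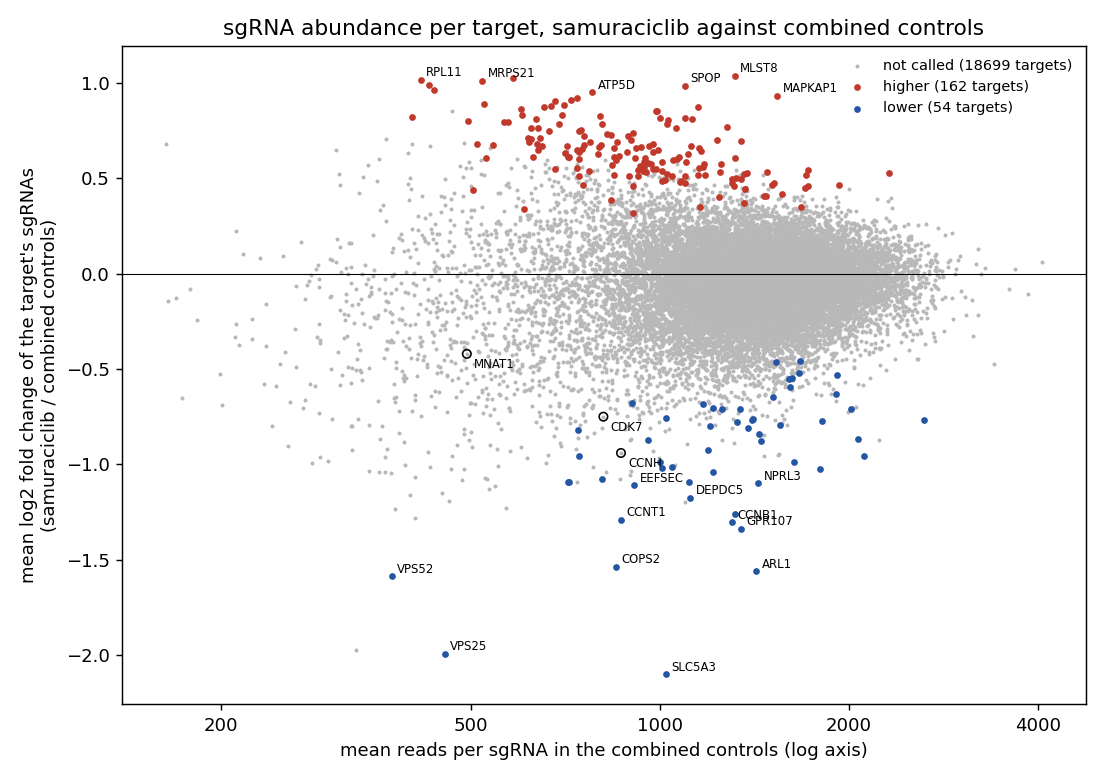
Mean log2 fold change of each target's sgRNAs (samuraciclib over combined controls, vertical axis) against the mean reads per sgRNA in the combined controls (horizontal log axis), 1 point per tested target, with the 162 targets called higher in red, the 54 called lower in blue, the rest in grey and the 3 CDK-activating kinase genes ringed in black. SLC5A3 is the lowest called target at −2.10 and MLST8 the highest at 1.04, and the spread of the grey points widens towards low read counts.

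The target of the compound did not pass the test. sgRNAs against CDK7 had a mean log2 fold change of −0.75 ± 0.98 (SD over 10 sgRNAs, 8 of them below 0; adjusted p = 0.208 by the permutation test). Its partners in the CDK-activating kinase, the trimer that phosphorylates cell-cycle CDKs and, within TFIIH, the RNA polymerase II tail, were at −0.94 ± 1.45 for cyclin H (CCNH) and −0.42 ± 0.76 for MNAT1, each over 10 sgRNAs, with adjusted p = 0.315 and 0.831 by the same permutation test. None of these 3 was called over all targets, whereas 2 of them were lower when adjusted over the list alone. Over the alternatives that refit the test, CCNH ran from −0.94 to −0.52 and MNAT1 from −0.42 to −0.26. The lowest single CCNH sgRNA was at −4.49. The trio's median of −0.75 lay at percentile 0.4 of matched random lists of 3 targets, and was −0.45 with 5 reads added to each count. Its median control level was −1.08 log2 against non-targeting sgRNAs, in a control column that includes days before the endpoint. The sgRNA nearest the CDK7 median, AGAACAGAGGCCTTAGAACA, had 29 reads in samuraciclib and 1078 in the controls (log2 −0.56), and single CDK7 sgRNAs ran from −2.47 to 0.58. In sums over its sgRNAs, CDK7 had 237 treated and 8123 control reads, a depth-scaled ratio of 0.713 (95% exact binomial interval 0.624 to 0.812, counting error only).

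sgRNAs against the mitochondrial ribosome, which translates the proteins encoded in mitochondrial DNA, moved up as a group. Of its 76 tested members 19 rose and none fell, 48 were higher when adjusted over the list alone, and 70 had a mean above 0. The list median was 0.40, at percentile 100 of 10000 random lists matched on control count. MRPS21 rose by 1.01 ± 0.46 with all 10 sgRNAs above 0, MRPS33 by 0.81 ± 0.77, MRPS25 by 0.80 ± 0.46 and MRPL47 by 0.78 ± 0.70 (SD over 10 sgRNAs each). The adjusted permutation p of these 4 ran from 0.00149 for MRPS21 to 0.0160 for MRPS33; with the median normal score MRPS33, MRPS25 and MRPL47 were no longer called.

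Complex I, the NADH dehydrogenase that starts the respiratory chain, followed with a median of 0.40, also at percentile 100. Of 39 tested members 5 rose and none fell, 28 were higher when adjusted over the list alone, and 35 had a mean above 0. The 5 were the subunits NDUFB6 (0.76 ± 0.58), NDUFA1 (0.67 ± 0.62), NDUFB11 (0.66 ± 0.53) and NDUFA3 (0.50 ± 0.33) and the assembly factor NDUFAF7 (0.56 ± 0.71), each over 10 sgRNAs. All 5 lost their call with the median normal score, with adjusted permutation p up to 0.0866, 0.0914, 0.339, 0.0914 and 0.302 in that order over the alternatives run. Other mitochondrial genes among the 12 targets with the highest fold changes were PTPMT1, a phosphatase of cardiolipin synthesis (0.99 ± 0.77), ROMO1, an inner-membrane protein (0.96 ± 0.67), ATP5D, the delta subunit of ATP synthase (0.95 ± 0.75), and VARS2, the mitochondrial valyl-tRNA synthetase (0.91 ± 0.68), over 10 sgRNAs each. ROMO1 was not called with the median normal score, with an adjusted permutation p from 0.000394 to 0.0560 over the alternatives.

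**Figure D2:**
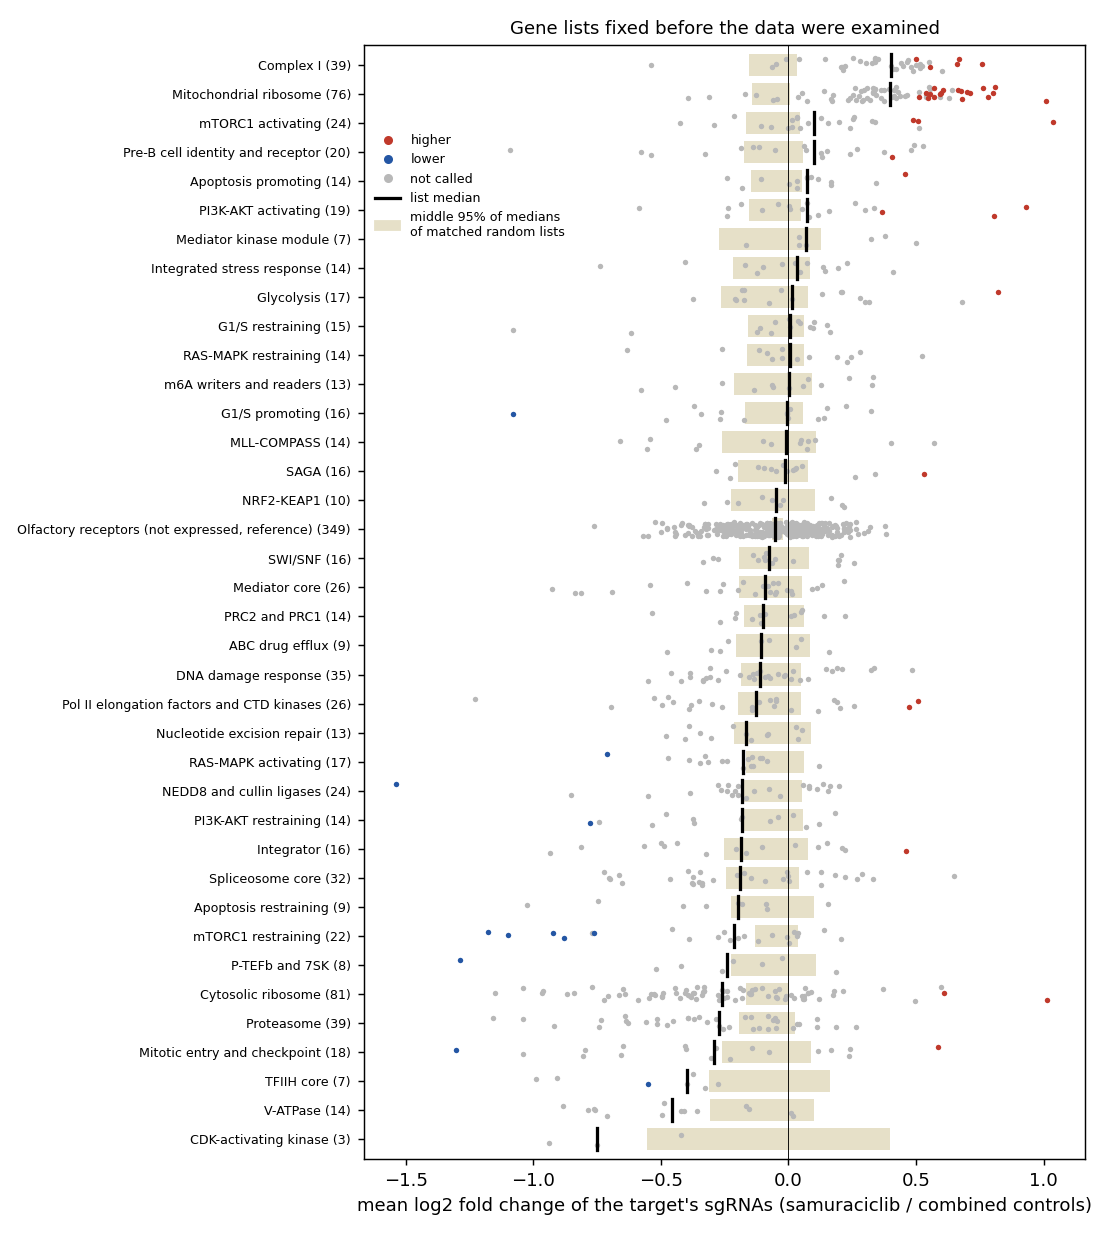
Mean log2 fold change of each tested target (samuraciclib over combined controls, horizontal axis) in gene lists fixed beforehand, ordered by list median, with the number of tested members in brackets; points are targets called higher (red), lower (blue) or not called (grey), black bars are list medians and shaded boxes span the middle 95% of medians of matched random lists. Complex I and the mitochondrial ribosome, both with a median of 0.40, stand at the top, and the CDK-activating kinase, at −0.75, at the bottom.

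Genes of the mTORC1 pathway, which couples nutrients and growth factors to cell growth, separated by the direction in which they act. Among 22 genes that restrain mTORC1, 5 fell and none rose (8 lower when adjusted over the list alone). Among these were DEPDC5 (−1.18 ± 0.88, 10 sgRNAs), NPRL3 (−1.10 ± 0.63, 8 sgRNAs) and NPRL2 (−0.92 ± 0.66, 10 sgRNAs), the members of the GATOR1 complex that switches off the Rag GTPases, and TSC2 (−0.88 ± 0.76, 10 sgRNAs), which inactivates RHEB. Its partner TSC1 was at −0.23 and was not called (adjusted permutation p = 0.758). Among 24 genes that activate mTORC1, 3 rose and none fell (5 higher when adjusted over the list alone): MLST8, a subunit shared by both mTOR complexes (1.04 ± 0.48), SEH1L, a member of GATOR2 and of the nuclear pore (0.51 ± 0.61), and the Ragulator subunit LAMTOR2 (0.49 ± 0.21), over 10 sgRNAs each. MTOR itself was at −0.11, RPTOR at −0.07 and RHEB at −0.21, none of them called. The restraining list had a median of −0.21 (percentile 0.02) and the activating list 0.10 (percentile 99.8).

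Among activating genes of PI3K-AKT signalling, members of mTORC2 and PDPK1 rose. RICTOR (0.81 ± 0.59, 10 sgRNAs) and MAPKAP1 (0.93 ± 0.43, 10 sgRNAs), both specific to mTORC2, which phosphorylates AKT, rose, as did PDPK1, the kinase that phosphorylates the AKT activation loop (0.37 ± 0.40, 17 sgRNAs). These were 3 of 19 activating genes (5 when adjusted over the list alone), with a list median of 0.07 at percentile 99.1 (97.0, inside the bounds, by normal score). The 14 genes that restrain the pathway had a median of −0.18 at percentile 1.81, with 1 called lower. AKT1 was at 0.34 and PIK3CD at 0.30, neither called. MLST8, MAPKAP1, RICTOR, DEPDC5 and NPRL3 reached the smallest adjusted p the permutation test could give, 0.000652, and MLST8 and MAPKAP1 had 9 and 10 of 10 sgRNAs above 0. The sgRNA nearest the MLST8 median, GCAGCTGATCCCTGAGCCCG, had 122 treated and 1469 control reads, and that nearest the DEPDC5 median, AGTGGTGATCACGCCCGGGG, had 19 and 850. NPRL2 lost its call with the median normal score (adjusted permutation p from 0.00175 to 0.168 over the alternatives). SEH1L and PDPK1 lost theirs under 3 alternatives each and LAMTOR2 under 2.

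**Figure D3:**
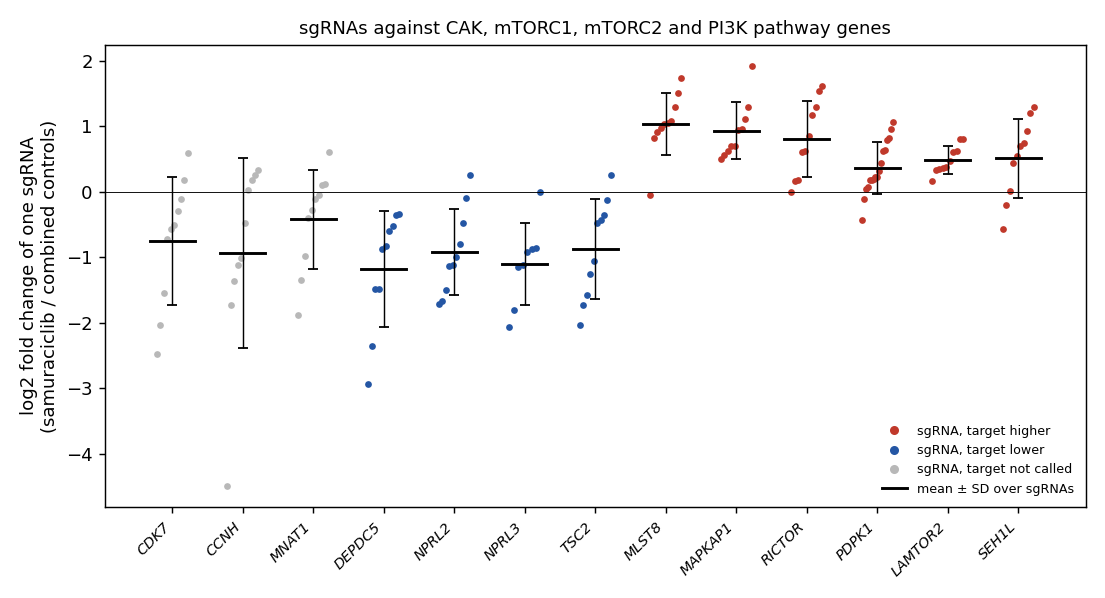
Log2 fold change of every sgRNA (samuraciclib over combined controls, vertical axis) against genes of the CDK-activating kinase, mTORC1, mTORC2 and PI3K pathways, coloured by whether the target was called higher (red), lower (blue) or not (grey), with black bars for the mean and whiskers for the SD over sgRNAs. MLST8 has 9 of 10 sgRNAs above 0 and DEPDC5 all 10 below 0, while those of CDK7 spread from −2.47 to 0.58.

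Among genes of transcription by RNA polymerase II, CCNT1, the cyclin of the elongation kinase P-TEFb, fell by 1.29 (log2, SD 1.01) with all 10 sgRNAs below 0, and its kinase CDK9 was at −0.52, not called. CCNT1 was 1 of 8 members of the P-TEFb and 7SK list, which had a median of −0.24 at percentile 1.96 (3.45, and so inside the bounds, when the median over sgRNAs was taken). The TFIIH core had a median of −0.40 at percentile 0.675, with all 7 members below 0 and 1 called lower, GTF2H5 (−0.55 ± 0.64). Of the 10 GTF2H5 sgRNAs 6 lay below 0 and 4 above, and its call was lost under 3 of 9 alternatives. Each list also had 1 gene lower when adjusted over the list alone. The median control level was −0.27 log2 against non-targeting sgRNAs for P-TEFb and 7SK and −0.97 for TFIIH. That of CCNT1 was −0.99, in a control column that includes days before the endpoint. Of 26 elongation factors and CTD kinases 2 rose (2 higher and 1 lower when adjusted over the list alone), AFF1 of the super elongation complex (0.51 ± 0.41, 9 sgRNAs) and RPRD1B, a CTD-binding protein (0.47 ± 0.65, 10 sgRNAs), and among 16 Integrator members INTS12 rose (0.46 ± 0.56, 10 sgRNAs). These 3 calls were lost under 2, 4 and 1 of the 9 alternatives. The elongation list median was −0.13 (percentile 16.4) although its mean normal score was 0.02.

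In the cell cycle, CCNB1, the cyclin that drives entry into mitosis with CDK1, fell by 1.30 (log2, SD 1.02) with all 10 sgRNAs below 0, and FZR1, an activator of the anaphase-promoting complex that targets cyclin B for degradation, rose by 0.59 ± 0.66 over 10 sgRNAs. These were the called members among 18 mitotic entry and checkpoint genes (1 higher and 2 lower when adjusted over the list alone), whose median was −0.29 at percentile 0.98 and −0.15 when the median over sgRNAs was taken. FZR1 lost its call with the null from non-targeting sgRNAs (adjusted permutation p from 0.0150 to 0.0501 over the alternatives). CDK6, a G1 kinase, fell by 1.08 (log2, SD 0.54) with all 10 sgRNAs below 0, a call that was lost with the median normal score and without its most distant sgRNA, and CDK4 was at 0.01. Control levels (log2 against non-targeting sgRNAs) were −0.40 for CCNB1, −1.09 for CDK6 and −1.16 as the mitotic list median. The control column includes days before the endpoint. The 16 genes promoting the G1/S step had a median of −0.01 (percentile 78.8), and the 15 restraining it 0.01 (percentile 81.9) with no called member.

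The apoptosis-promoting, RAS-MAPK activating and pre-B cell lists held 1 called gene each. CYCS, the cytochrome c that triggers the apoptosome and also carries electrons in respiration, rose by 0.46 ± 0.84 over 12 sgRNAs (call lost under 3 alternatives) in a list of 14 apoptosis-promoting genes with a median of 0.07 at percentile 99 (2 higher when adjusted over the list alone). PTPN11, the phosphatase SHP2, fell by 0.71 (log2, SD 0.59) with all 10 sgRNAs below 0, in a list of 17 RAS-MAPK activators with a median of −0.18 at percentile 1.85 (2.88 by normal score) and 1 lower when adjusted over the list alone. With the median normal score PTPN11 was not called (adjusted permutation p from 0.00946 to 0.169 over the alternatives). IKZF1, the lymphoid transcription factor Ikaros, rose by 0.40 ± 0.43 over 14 sgRNAs, in a list of 20 pre-B cell identity and receptor genes with a median of 0.10 at percentile 99.7, which fell back inside the bounds under 3 alternatives (95.8 by normal score). Adjusted over the list alone, 5 pre-B genes were higher and 2 lower.

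Of the called targets, SLC5A3, a myo-inositol transporter, had the lowest fold change. Its sgRNAs fell by 2.10 (log2, SD 1.37) with 10 of 10 below 0, from 10230 control reads to 129 treated reads, a depth-scaled ratio of 0.308 (95% exact binomial interval 0.257 to 0.367). Also lower were the ESCRT-II subunit VPS25 (−1.99 ± 1.34), VPS52 of the GARP and EARP tethers (−1.59 ± 1.16), the Golgi GTPase ARL1 (−1.56 ± 0.63) and the Golgi protein GPR107 (−1.34 ± 1.07), each with 10 of 10 sgRNAs below 0. COPS2 of the COP9 signalosome, which removes NEDD8 from cullins (−1.54 ± 2.01), the transcription factor USF2 (−1.26 ± 1.55) and EEFSEC, the selenocysteine elongation factor (−1.11 ± 1.36), had 9 of 10 below 0. VPS25, VPS52 and EEFSEC lost their calls with the median normal score. Control levels (log2 against non-targeting sgRNAs) were −1.92 for VPS25, −2.21 for VPS52, −1.02 for COPS2 and −0.92 for EEFSEC. They were −0.75 for SLC5A3, −0.39 for USF2, −0.35 for GPR107 and −0.27 for ARL1. The control column includes days before the endpoint, so loss of a knockout over time cannot be told apart from an effect of the compound here. With other settings the fold changes of VPS25, VPS52, COPS2, USF2 and EEFSEC came as close to 0 as −0.80, −0.74, −0.69, −0.76 and −0.63.

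On the higher side, UBE2G2, a ubiquitin-conjugating enzyme of the endoplasmic reticulum (1.03 ± 0.78), SPOP, a substrate adaptor of CUL3 ligases (0.98 ± 0.35), and PMVK, phosphomevalonate kinase (0.92 ± 0.45), rose with 10 of 10 sgRNAs each. The pre-mRNA splicing factor PRPF39 (0.90 ± 0.53, 10 sgRNAs), the hexokinase HK2 (0.82 ± 0.88, 10 sgRNAs) and USP22, the deubiquitinase of SAGA (0.53 ± 0.43, 10 sgRNAs), also rose. HK2 was the only called gene of 17 in glycolysis (2 higher when adjusted over the list alone), and USP22 of 16 in SAGA (2 higher when adjusted over the list alone).

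Lists of cellular machinery needed by most cells lay lower, with few or no called members. The V-ATPase, the proton pump that acidifies lysosomes, had a median of −0.46 over 14 members (percentile 0.07), the proteasome −0.27 over 39 (percentile 0.07) and the cytosolic ribosome −0.26 over 81 (percentile 0). None of the V-ATPase or proteasome members was called, over all targets or adjusted over the list alone. In the cytosolic ribosome 2 rose and none fell (3 higher when adjusted over the list alone): RPL11, which also binds MDM2 (1.01 ± 0.74, 10 sgRNAs), and RPS25 (0.61 ± 0.60, 18 sgRNAs), with calls lost under 2 and 4 alternatives and the fold change of RPL11 down to 0.64. The sizes moved with the setting: with 5 reads added to each count the medians were −0.25 for the V-ATPase and −0.07 for the cytosolic ribosome, and with at least 100 control reads per sgRNA −0.42 and −0.17, all still shifted. With the median over sgRNAs the proteasome was at −0.05, inside the bounds (percentile 9.57). The control level of these sgRNAs was already low, with a list median of −1.52, −1.34 and −1.54 log2 against non-targeting sgRNAs for V-ATPase, proteasome and ribosome, in a control column that includes days before the endpoint.

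Of the 39 lists, 23 stayed inside the bounds, some of them near an edge. The NEDD8 and cullin ligase list, in which COPS2 was the only called gene of 24, had a median of −0.18 (percentile 2.69). Apoptosis-restraining genes had −0.20 (percentile 5.11), nucleotide excision repair −0.17 (7.49), the spliceosome core −0.19 (9.84, with a mean normal score of 0.02) and Integrator −0.19 (10.5). ABC drug efflux transporters had −0.11 (22.6), with ABCB1, the multidrug transporter, at −0.27 and ABCG2 at −0.08, neither called. Further medians were −0.10 for PRC2 and PRC1, −0.11 for the DNA damage response, −0.09 for core Mediator, −0.07 for SWI/SNF, −0.05 for NRF2-KEAP1, −0.01 for MLL-COMPASS, −0.01 for SAGA, 0.00 for m6A writers and readers, 0.01 for RAS-MAPK restraining genes, 0.01 for glycolysis, 0.03 for the integrated stress response and 0.07 for the Mediator kinase module. Under other settings some of these 23 lists lay outside the bounds, glycolysis under 3 of 7 (0.17 with a pseudocount of 5, percentile 99.9), RAS-MAPK restraining genes under 2 (0.12 with the median over sgRNAs, percentile 99.0) and the integrated stress response under 1 (0.18 with the median over sgRNAs, percentile 99.4). Integrator, NEDD8 and cullin ligases and apoptosis-restraining genes were lower under 2 settings each, PRC2 and PRC1, nucleotide excision repair and the spliceosome lower under 1 each, and the Mediator kinase module higher under 1. Adjusted over the list alone, 3 members of core Mediator, 2 of the apoptosis-restraining list and 1 each of Integrator, NEDD8 and cullin ligases, RAS-MAPK restraining and both G1/S lists were lower, and 1 member of Integrator was higher. Olfactory receptors, which are not expressed in these cells and serve as a background, had a median of −0.05 over 349 targets (percentile 18.1) with none called and 18 (5.16%) at an unadjusted permutation p below 0.05.

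The spread between sgRNAs was larger than counting alone gives. The SD of log2 fold changes over non-targeting sgRNAs was 0.52, against 0.21 expected from counting at the median treated depth, and the spread over all sgRNAs was 1.07 among the 10% of sgRNAs with the lowest control counts and 0.26 among the 10% with the highest. When each target's sgRNAs were divided at random into equal parts, the fold changes of the parts correlated across 18915 targets with Pearson's r of 0.16 and Spearman's rho of 0.11, where targets are not independent replicates. Both parts were above 0 for 65 of 76 mitochondrial ribosome and 33 of 39 complex I members, against 58 of 349 olfactory receptors. Both parts come from the same columns, so these counts restate the list shifts. Within these lists Pearson's r between the parts was 0.13, 0.43 and 0.008 in that order, and Spearman's rho 0.21, 0.28 and 0.02. The parts thus agreed little on which mitochondrial ribosome members rose, and somewhat more on which complex I members did. In simulated libraries of this depth, 72% of 50 targets raised by 0.5 and 66% of 50 lowered by 0.5 on the log2 scale were called. All of those changed by 1 were called, and the remaining changes of 0.5 were not. The simulated sgRNAs of a target shared 1 change, with an extra SD of 0.31, and inactive sgRNAs were not simulated. Real targets can spread more, such as CCNH (−0.94 ± 1.45, not called) and COPS2 (−1.54 ± 2.01, called). The test ranks sgRNAs and uses neither the mean fold change nor its SD. NPRL2 (−0.92 ± 0.66), with a mean fold change like that of CCNH, was called at a mean normal score of −1.33, against −0.79 for CCNH. The simulated shares therefore need not hold for real targets.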

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

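The test in this part was chosen after the data had been seen. Among the 614 sgRNAs left out of every comparison for having fewer than 20 control reads, 16 had more treated reads than their share of control reads gives (one-sided exact binomial test, Benjamini-Hochberg adjusted over the 614). The lowest adjusted p of this exact test was 0.000287, for an sgRNA against PRKG2 with 8 treated and 12 control reads, and 8 was the highest treated count in the set. These sgRNAs had been selected by their low control counts.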

How the results depend on the processing

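Tests with ranks in GC bins, lists without centring or centred on olfactory receptors, and lists by normal score were chosen after seeing the data. No called result reversed. Called targets numbered between 171 and 281 (main 216) except in these settings: with the median normal score 109 were called (78 higher, 31 lower; 103 shared with the main set), and at a threshold of 0.01 there were 101 (74 higher, 27 lower). The null from non-targeting sgRNAs gave 84 called lower against 54. Ranks without bins shared 176 of their 281 calls with the main set. Of 53 called named genes, 25 kept the call under all 9 alternatives that refit the test, and 28 lost it at least once.

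Lists that left the shifted state were P-TEFb and 7SK with the median over sgRNAs (−0.14), the proteasome with the same setting (−0.055), the pre-B list with a pseudocount of 5 (0.063), with the median over sgRNAs (0.10) and by normal score (0.18), and by normal score PI3K-AKT activating (0.17) and RAS-MAPK activating (−0.21). Lists that became shifted were, with the median over sgRNAs, RAS-MAPK restraining (0.12), PRC2 and PRC1 (−0.12), nucleotide excision repair (−0.17), the integrated stress response (0.18) and glycolysis (0.17); with a pseudocount of 5, apoptosis restraining (−0.16) and glycolysis (0.17); with at least 100 control reads, NEDD8 and cullin ligases (−0.18). Against unmatched random lists, NEDD8 and cullin ligases (−0.18), Integrator (−0.19) and the spliceosome (−0.19) were lower, since such lists no longer share their low control counts. By normal score, the Mediator kinase module (0.38), RAS-MAPK restraining (0.23) and glycolysis (0.31) were higher, and Integrator (−0.21) and apoptosis restraining (−0.37) lower. The cause was not tested for the other changes. The other 250 values of lists under alternatives stayed shifted or not shifted as before, although some medians inside the bounds changed sign, such as SWI/SNF (−0.07 to 0.12) and core Mediator (−0.09 to 0.015) with the median over sgRNAs.

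The correlation between random parts of the sgRNAs was 0.18 with a pseudocount of 5 (0.16 otherwise; SD over splits 0.0053). No paired analysis was possible because the control libraries were pooled into 1 column, and no library could be left out or regrouped. The depth of the treated library, a median of 48 reads per sgRNA, is 1 limit on what can be called, beside the spread between sgRNAs.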

Other observations

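The gene groups of this paragraph and the next were chosen after the called targets had been seen, as were the tests of all lost sgRNA sets rising, of growth gain in the controls and of skewed fold changes below; the tests of slow loss, of GC content and of the uncalled members of each group were set out before their results. Members of further mitochondrial groups rose. Of 20 mitochondrial aminoacyl-tRNA synthetases and amidotransferase subunits 14 rose, among them FARS2 (0.79 ± 0.44) and YARS2 (0.76 ± 0.47, SD over 10 sgRNAs each). Complex III had 5 of 15 members higher, such as UQCRC1 (0.75 ± 0.86, 10 sgRNAs), complex IV 4 of 30, such as COA3 (0.78 ± 0.56, 10 sgRNAs), ATP synthase 5 of 18, such as ATP5C1 (0.82 ± 0.58, 10 sgRNAs), and coenzyme Q synthesis 3 of 14, such as COQ6 (0.86 ± 0.62, 10 sgRNAs). Complex II (8 members) and mitochondrial protein import (21) had none called. The median normal score of the members that were not called lay at percentile 100 of matched random lists of uncalled targets for the synthetases, 99.95 for complex III, 100 for complex IV, 99.98 for ATP synthase, 97.6 for complex II and 100 for import, all above the upper bound, while for coenzyme Q synthesis it lay at 79.2. Without the added test, the fold change median of complex II (0.12) stood at percentile 96.5, inside the bounds. Of 6 Elongator subunits, ELP5 (0.59 ± 0.41) and ELP6 (0.61 ± 0.36, 10 sgRNAs each) rose, and the uncalled members lay at percentile 94.1.

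Groups with called members on the lower side were chosen in the same way. The CTLH ubiquitin ligase had 4 of 12 members lower: MAEA (−1.03 ± 0.98, 10 sgRNAs), YPEL5 (−0.87 ± 0.32, 10 sgRNAs), WDR26 (−0.84 ± 0.79, 9 sgRNAs) and its E2 enzyme UBE2H (−0.63 ± 0.49, 10 sgRNAs), with the uncalled members at percentile 52.5. In selenocysteine incorporation, EEFSEC, SEPSECS (−1.09 ± 1.11, 10 sgRNAs) and the selenoprotein GPX4, which removes lipid peroxides (−1.02 ± 1.01, 14 sgRNAs), fell and TRIT1, a tRNA-modifying enzyme that also acts on mitochondrial tRNAs, rose (0.66 ± 0.57, 10 sgRNAs), with the uncalled members at percentile 0. VPS52 and TSSC1 (−1.01 ± 0.63, 10 sgRNAs) fell among 6 GARP and EARP members (uncalled at 0.92), and VPS25 and CHMP6 (−1.09 ± 1.03, 10 sgRNAs) among 22 ESCRT members (uncalled at 0.26). GATOR1 and KICSTOR had 4 of 7 lower, with the uncalled members at percentile 0.02. In mTORC2, 3 of 6 rose (MLST8, RICTOR and MAPKAP1), and the others lay at percentile 68.0. For coenzyme Q, Elongator, CTLH and mTORC2 the uncalled members leave open whether the whole group moved.

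The first pattern weighed is the rise of the mitochondrial ribosome and complex I. A technical reading is that cells doubling more slowly in the compound would lose every harmful knockout less. Without other differences, it requires the cytosolic ribosome, proteasome and spliceosome to rise too. Their median normal score was −0.12 (95% bootstrap interval −0.16 to −0.05, 152 targets) against 0.79 (0.72 to 0.88, 115 targets) for the mitochondrial lists. Their control level was lower (−1.52 against −0.96 log2). The rise was thus not shared by all lost sgRNA sets in these columns. The control column also holds days before the endpoint, when core knockouts would be less depleted, which could hide a rise. The comparison therefore cannot decide on this reading. GC content of the sgRNAs is argued against, since all 24 called members kept their call with ranks in GC bins. A slower loss that is cut short in the compound may apply only to mitochondrial genes and remains open. Spearman's rho between control level and score was −0.10 (−0.29 to 0.08). The score was ranked within bins of control count, where the spread is larger at low counts. An equal fold change thus scores less at a low control level, so this rho cannot decide. A reduced need for respiration under the compound is likewise open, and untested.

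The second pattern is the fall of negative regulators of mTORC1 (5 of 22 called lower) and of PI3K-AKT (1 of 14 called lower). If their loss sped growth in the controls and fewer doublings in the compound reduced this gain, their control level should exceed that of unexpressed genes. The median control level of the 6 called genes was −0.33 (log2 against non-targeting sgRNAs) against −0.12 for olfactory receptors. It lay at percentile 9.34 of random lists of 6 receptor targets, and the middle 95% of their medians ran from −0.43 to 0.15. The called genes' median was below that of the receptors but inside this range. Their level could thus not be told apart from that of 6 receptor targets, so a gain is neither shown nor excluded. This explanation and a greater sensitivity to the compound of cells with active mTORC1 or PI3K signalling, the biological hypothesis that the treatment offers, cannot be told apart with 6 genes and pooled controls.

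The third pattern is the lower position of ribosome, proteasome and V-ATPase lists. Skewed fold changes at few control reads were tested by ranks within bins of control count: the median normal score of the 134 pooled members, −0.15, was at percentile 0 of matched random lists, which argues against skew as the whole cause, although the proteasome alone lost its shift with the median over sgRNAs. A difference in time is a candidate explanation, since the treated library is from day 8 and the control column also holds spinner flask libraries from days 0, 2, 4 and 6, in which such knockouts would be less depleted. It could not be tested directly on pooled controls; the spliceosome list, with a control level of −1.81, stood at percentile 9.84 and a mean normal score of 0.02. A biological effect of the compound on these knockouts stays open too.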
